A study of Mus musculus with 40 samples.

How the data were processed

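RNA was sequenced from 5 tissues of C57BL/6J mice at 60 days of age, 24 hours after acute activation of p53, per the labels. The tissues were pancreas, kidney, ovary, heart and small intestine. Each gave 3 libraries of Tg mice, which carry 1 working copy of Mdm2 and a ubiquitously expressed Cre recombinase (Mdm2+/- Cag-CreER), and 5 libraries of FMTg mice, in which Mdm2 is lost (Mdm2FM/- Cag-CreER). The 40 libraries came from 13 mice, 3 Tg and 10 FMTg. The same 3 Tg mice gave every Tg library, and most FMTg mice gave more than 1 tissue.

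Reads were aligned with STAR 2.6.0b to the mouse build GRCm38 and processed with DESeq2, per the submitters' processing notes. The notes do not name the read counter, the annotation release, the strand setting or the filter that left 18024 genes. The deposited values are log2 values on a variance-stabilised scale, computed over all 40 libraries together after division by 1 size factor per library. A gene without reads has the same lowest value, 1.65, in every library. Inverting the transformation gave whole read numbers for 100% of the values with a tolerance of 0.01, and the largest distance from a whole number was 1.16e-07. The recovered totals ran from 7.16 to 29.0 M reads per library. Of the 18024 genes, 17983 are protein coding in GENCODE M21 and 52 had no read in any library. Gene positions are those of GENCODE M21 on GRCm38. Because strand is not stated, reads of overlapping genes on opposite strands are possibly counted together, and near-identical copies such as the globin genes Hba-a1 and Hba-a2 share reads.

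In each tissue the 8 libraries were compared with limma 3.58.1 in R 4.3.3 (linear model with genotype as the only term, moderated statistics with a mean-variance trend) on the deposited values. Genes with a tissue mean at least 1 above the lowest value were tested, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 changes are FMTg minus Tg and are given with the standard error of the limma model. Folds are powers of 2 of those differences, which are compressed toward 1 for genes with few reads. All p values of single genes below come from limma unless an exact permutation test is named. Exact tests were two-sided and ran over the 56 ways to divide 8 libraries into 3 and 5, so the smallest p they can give is 0.0179.

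A set of 46 gene lists was fixed before the data were examined. It holds 5 lists of p53 targets, pathway lists, and markers of cell types of these tissues and of cells that a dissection could include. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 222 pairs of list and tissue. Of these, 80 pairs passed and none passed with a correlation estimated from the data, so the list results rest on the preset value. The lists described below are a selection, and some pairs that passed are not named. The named lists therefore do not stand for all that passed. The rotation test fry was run beside camera, but its results are not given here and no statement below rests on it. Member counts are given adjusted over the list alone and over all genes tested. A score of the p53 targets was computed per library as the mean difference of the 62 tested targets from the Tg mean of the tissue.

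A single limma model of all 40 libraries, with mouse as a random block (correlation 0.233, statmod 1.5.0), gave an F test of differences between tissues in the genotype effect. The mean of the 5 tissue effects was added after the data were seen. The genes named per tissue were chosen by a rule fixed before the data were examined: Mdm2 and Trp53, the 10 largest rises and 10 largest falls among called genes whose FMTg and Tg libraries do not overlap, without predicted gene models, and up to 4 members with the smallest p of each list described. Across tissues the 10 genes with the smallest p for differing were taken, of which 1 is not reported here, and neither is 1 member of the B cell list. The 20 genes of largest mean effect and all 7 named genes with a lower mean effect were chosen after their values were seen.

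The procedure was tested on simulated reads drawn from the means and depths of these libraries. It called 45.4% of genes changed 4-fold in the pancreas, 89.7% in the kidney, 63.9% in the ovary, 51.0% in the heart and 68.7% in the small intestine. For genes changed 2-fold the shares were 15.2%, 59.6%, 24.0%, 25.5% and 29.3%. With no gene changed it made 0 calls in each tissue. The model of all tissues called 92.5% of genes changed 4-fold in every tissue on the mean effect, together with 28 other genes, and 1 gene with no gene changed. Its F test called 76% of genes changed 4-fold in the kidney only (152 genes), 0.5% of genes changed in every tissue and 0.661% of the other genes (112) as differing. With no gene changed in any tissue it still called 22 of 17335. In simulated reads it therefore did not hold the error rate that its adjusted p states. Each simulation was 1 draw. Its libraries were independent of each other, and the model of all tissues was fitted to them without mouse correlation, unlike the real data.

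The labels give no batch. Mouse numbers run from 1964 to 2972. The FMTg libraries of mice numbered 1964 to 2119, called low-numbered here, were set apart after the data were seen, because their values spread more widely and held many more genes without reads. The numbers alone do not set that limit, since their widest gap lies above 2235. In every tissue 2 of the 5 FMTg libraries and no Tg library came from low-numbered mice. Reads of Y-linked genes marked 5 of the 10 FMTg mice as male and no Tg mouse, and all ovary mice are female. Males gave 3 of the 5 FMTg libraries in the pancreas and 2 of 5 in the kidney, heart and small intestine. FMTg Pancreas replicate 1 is male and not low-numbered, so setting the low-numbered mice apart does not remove the difference in sex there. Only the subset of mice with an ovary library is all female in that tissue. Genotype was compared among the mice other than the low-numbered ones as an alternative, by leaving those out or by adding a term for them. Both were chosen after the data were seen, as was limma's voom method on the recovered reads. Alternatives fixed beforehand were other filters, other scalings, no variance trend, library weights, 1 model for all libraries, a replicate block, subsets of mice, the back-transformed scale with a pseudocount of 1, an estimated correlation for lists, and each library left out in turn. In the model of all 40 libraries 1 replicate number of 1 genotype was left out of every tissue together. Figures were drawn with matplotlib 3.10.9.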

Results

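The series measured messenger RNA in 5 tissues of adult mice 24 hours after p53 was activated by loss of Mdm2, the ubiquitin ligase that holds p53 in check. It asks which genes respond in each tissue. There were 8 libraries per tissue, 3 from Tg mice that retain Mdm2 and 5 from FMTg mice that lost it. Depth was 7.16 to 13.9 M (mega) reads in the pancreas, 14.6 to 27.9 M in the kidney, 8.97 to 23.0 M in the ovary, 15.3 to 29.0 M in the heart and 14.4 to 23.3 M in the small intestine. The FMTg libraries of the low-numbered mice (replicate 4 and replicate 5 of each tissue), set apart for their many genes without reads, showed fewer genes at an equal depth of 7.16 M reads than every other library of their tissue. In the pancreas these were 12004 and 13771 genes, against 15009 to 16080 in the other 6 libraries.

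**Figure D1:**
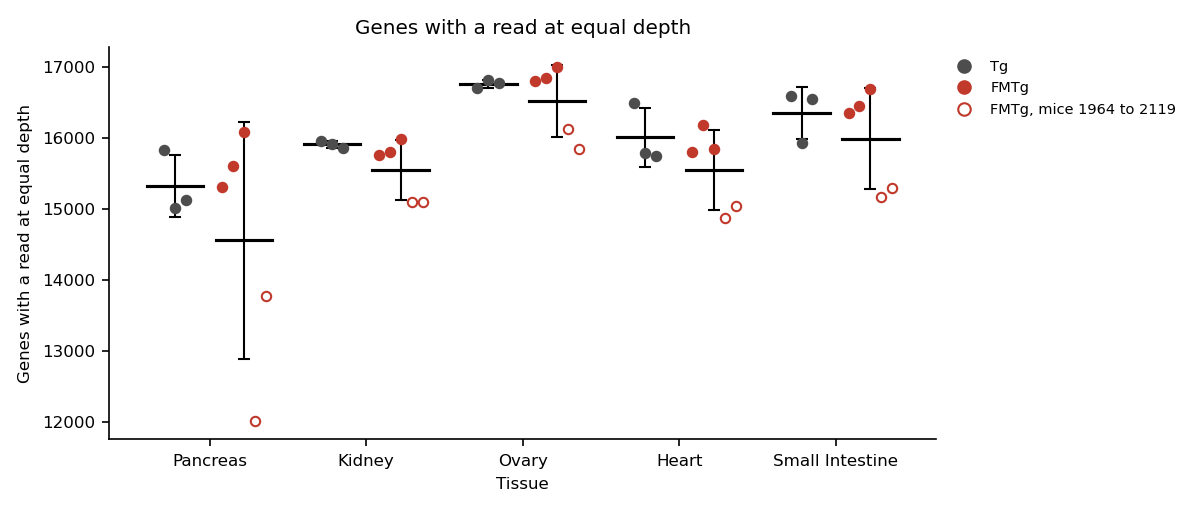
Genes with at least 1 read after each library was scaled to the same depth (y axis, number of genes) by tissue (x axis). Each point is a library, bars are mean and SD, and open points are the low-numbered FMTg mice, which lie below all other libraries of their tissue (in the pancreas at 12004 and 13771 genes).

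Mdm2 (ENSMUSG00000020184.15, chromosome 10, 117688875 to 117710758) had higher normalised values in FMTg than in Tg libraries in every tissue. The labels do not say which part of the gene was removed, and Mdm2 is itself a p53 target, so the gene total does not check the deletion. Its log2 change was 2.00 ± 0.17 (SE, n = 5 FMTg and 3 Tg) in the kidney, a 3.99-fold rise with an adjusted p of 6.85e-04. In the pancreas it rose by 1.59 ± 0.25, or 3.01-fold, with an adjusted p of 0.0286. This pancreas call ended when single libraries were left out, in 6 of 8 cases, with an adjusted p of up to 0.190. The change was 1.30 ± 0.21 in the small intestine (adjusted p = 0.558), 0.80 ± 0.26 in the heart (0.760) and 0.77 ± 0.23 in the ovary (0.515), which did not pass the test over all genes. All 5 FMTg libraries lay above all 3 Tg libraries in each tissue. The exact permutation p for Mdm2 alone was 0.0179 in the pancreas, kidney and small intestine, 0.0357 in the heart and 0.0536 in the ovary. Trp53 (ENSMUSG00000059552.13, chromosome 11, 69580359 to 69591873), which encodes p53, showed log2 changes from -0.26 to 0.35, none past the threshold.

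**Figure D2:**
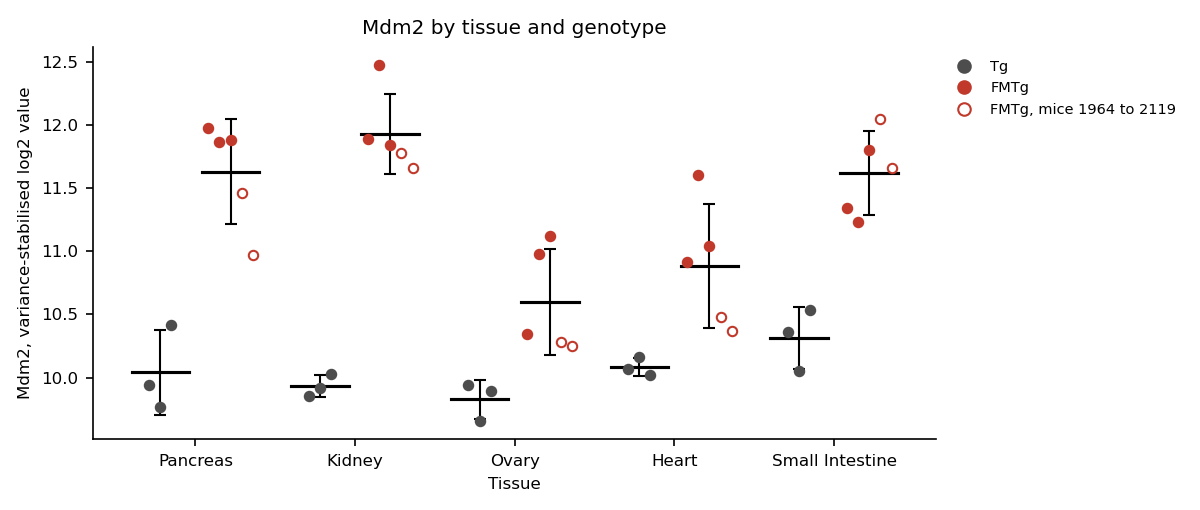
Deposited log2 value of Mdm2 (y axis, variance-stabilised scale) by tissue (x axis). Points are libraries, bars are mean and SD, open points are low-numbered FMTg mice. The kidney FMTg libraries lie between 11.66 and 12.48 and the Tg libraries between 9.85 and 10.03.

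In the pancreas 64 genes rose, 20 of them on the fixed lists of p53 targets, and 4 fell. Trp53inp1, a stress protein that promotes p53 activity and autophagy, rose 7.24-fold (log2 2.86 ± 0.16, adjusted p = 1.75e-04). Psrc1, a spindle-associated protein, rose 8.47-fold (3.08 ± 0.22, adjusted p = 6.52e-04), and Gtse1, which binds p53 and moves it out of the nucleus, rose 7.39-fold (2.89 ± 0.29, adjusted p = 0.00494). Inka2, an inhibitor of the kinase Pak4, and Pidd1, the core of the PIDDosome that activates caspase-2, rose 7.77-fold and 6.07-fold. Ddit4l, an inhibitor of mTOR signalling, Inmt, a methyltransferase of small amines, and Prox1, a homeodomain factor of pancreatic and lymphatic development, rose by 2.66 ± 0.40, 2.61 ± 0.33 and 2.50 ± 0.31. Sp5, a transcription factor downstream of Wnt, rose by 4.29 ± 0.61 from 3.10 to 180 normalised reads. Obp2b, a lipocalin, had 1 read over the 3 Tg libraries and 271 over the 5 FMTg libraries, a ratio per read of 154 with an exact 95% interval of 27.3 to 6090 that covers counting error only. Psrc1, Gtse1 and Trp53inp1 kept their calls in all 8 fits that left out a library, Inka2 in 6, Inmt and Prox1 in 5, Pidd1 in 3, Sp5 and Ddit4l in 2 and Obp2b in 1. Without the low-numbered mice Obp2b did not pass (adjusted p = 0.0693).

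Altogether 68 of 15262 genes tested changed in the pancreas, 64 higher and 4 lower. All 4 that fell are named here. Actn1, an actin crosslinker, fell by 1.41 ± 0.24. Vipr1, the receptor of vasoactive intestinal peptide, fell by 1.31 ± 0.19. Muc1, a membrane mucin of ductal epithelium, fell by 1.08 ± 0.17, and Chd3, a chromatin remodeller, fell by 0.94 ± 0.16. Their adjusted p ran from 0.0197 (Vipr1) to 0.0453 (Actn1), and none passed without the low-numbered mice (0.0567 for Vipr1 to 0.0880 for Actn1). There were 109 changed genes without the low-numbered mice, 98 higher and 11 lower, 55 of them among the 68. That fit still held the male FMTg replicate 1. Among mice with an ovary library, all female, 2 genes changed (FMTg replicate 2 and FMTg replicate 3 against the 3 Tg libraries). Without Tg replicate 1 or Tg replicate 2 the count was 9 in each case, and without Tg replicate 3 it was 25. It was 29, 42 and 43 without FMTg replicate 1, FMTg replicate 2 and FMTg replicate 5. Library weights gave 568 genes, 1 model for all libraries 390, and the fit without the variance trend 10.

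Of the cell-type lists of the pancreas described here, erythroid, endothelial and islet hormone genes passed at the preset correlation, and none passed with an estimated correlation. Of 6 erythroid genes, 5 rose adjusted over the list alone and 2 over all genes, with a median log2 change of 1.89. The beta globin Hbb-bs rose by 2.10 ± 0.29, the alpha globin Hba-a1 by 2.31 ± 0.35 and Alas2, the first enzyme of heme synthesis in red cells, by 2.08 ± 0.64. The adjusted p of this list was 2.44e-07 at the preset correlation and 0.173 with an estimated correlation. All 8 endothelial genes had higher FMTg means (median 0.54), with no member past the threshold; Kdr, a receptor of vascular growth factor, differed by 0.65 ± 0.20. This list had an adjusted p of 4.05e-04 at the preset correlation and 0.122 with an estimated correlation. The acinar genes, which encode digestive enzymes and their regulators, showed a median of 0.29 with 0 of 19 past the threshold (adjusted p = 0.438). Of 19 duct and acinar-to-ductal change genes, 1 rose and 5 fell adjusted over the list alone, with a camera adjusted p of 0.461. The matrix protein Spp1 rose by 1.35 ± 0.27, while the mucin Muc1, the chaperone Clu (-1.18 ± 0.28) and the keratin Krt18 (-0.88 ± 0.23) fell. Clu and Krt18 did not pass without Tg replicate 2 or Tg replicate 3, and Alas2 did not without Tg replicate 2. Islet hormone genes had a median of 0.68 (adjusted p = 0.00342, 0.717 with an estimated correlation), with no member past the threshold. Without the low-numbered mice the median was 0.31 (adjusted p = 0.281), and without Tg replicate 3 it was 0.53 (0.0527). The exact permutation p of the list mean was 0.161 for islet hormone genes and 0.0357 each for erythroid and endothelial genes.

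The kidney had 93 genes that rose, 32 of them on the fixed lists of p53 targets, and 2 that fell. Gtse1 (chromosome 15) rose by 4.91 ± 0.26 on the log2 scale (adjusted p = 2.77e-05), Psrc1 (chromosome 3) 13.8-fold (3.79 ± 0.19) and Inka2 (chromosome 3) 10.3-fold (3.37 ± 0.16). Zfp365, a zinc finger protein linked to genome stability, rose by 3.29 ± 0.25. Eda2r, a death-domain receptor of the tumour necrosis factor family, rose by 3.17 ± 0.16, and Ddias, a suppressor of damage-induced apoptosis, by 3.15 ± 0.21. Cdkn1a, the inhibitor p21 of cyclin-dependent kinases, rose 8.12-fold (3.02 ± 0.24, adjusted p = 5.04e-04). Sec14l5, a lipid transfer protein, rose by 3.12 ± 0.35, the cytokine Lif by 2.63 ± 0.30 and Ano3, a membrane protein of the anoctamin family, by 2.53 ± 0.30. These 10 calls held in all 8 fits that left out a library. The 2 genes that fell were Serpina3m, a serpin (-2.09 ± 0.35, adjusted p = 0.0337), and Ccl28, an epithelial chemokine (-1.54 ± 0.27, adjusted p = 0.0458). Each of these falls kept its call in 2 of the 8 fits, and neither passed without the low-numbered mice (0.0641 and 0.144).

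In all, 95 of 15415 genes changed in the kidney, 93 higher and 2 lower. With the low-numbered mice left out 123 changed, 120 higher and 3 lower, and 84 of the 95 were among them. Leaving out a Tg replicate gave 47, 46 and 52 genes for Tg replicate 1, Tg replicate 2 and Tg replicate 3, library weights gave 211 and 1 model for all libraries 59. Of 7 neutrophil genes 3 fell adjusted over the list alone (median -0.91): the calprotectin genes S100a9 (-1.29 ± 0.29) and S100a8 (-1.10 ± 0.34) and the resistin-like gene Retnlg (-1.33 ± 0.43). The list had an adjusted p of 4.62e-04 at the preset correlation and 0.580 with an estimated correlation, and no member passed without the low-numbered mice. S100a8 and Retnlg also lost their calls without Tg replicate 1, FMTg replicate 1, FMTg replicate 3, FMTg replicate 4 or FMTg replicate 5. Proximal tubule genes had a median of 0.43 (adjusted p = 0.00179, 0.584 with an estimated correlation), with no member past the threshold. Without the low-numbered mice, which are male in this tissue, the median was 0.20 (adjusted p = 0.130). The exact permutation p of the list mean was 0.0536 for neutrophil genes and 0.161 for proximal tubule genes. Kidney injury genes had a median of -0.27 and no member past the threshold (adjusted p = 0.439); Havcr1, the injury marker KIM-1, differed by 1.99 ± 1.10.

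The p53 targets rose as a group in every tissue. The 5 lists fixed beforehand hold 62 tested genes. Adjusted over the list alone, 35 rose in the pancreas, 39 in the kidney, 13 in the ovary, 22 in the heart and 29 in the small intestine, and 0 fell. Adjusted over all genes tested these numbers were 20, 32, 0, 3 and 0. The median log2 changes were 1.06, 0.95, 0.36, 0.68 and 0.71 in the same order. Camera gave adjusted p values from 1.51e-46 in the kidney to 9.49e-12 in the ovary at the preset correlation. With an estimated correlation the adjusted p values were 0.0635, 0.0635, 0.143, 0.108 and 0.0665. The score per library rose by 0.88 in the pancreas (exact permutation p = 0.0179, the smallest possible), 1.07 in the kidney (0.0179), 0.42 in the ovary (0.0357), 0.72 in the heart (0.0179) and 0.74 in the small intestine (0.0179).

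**Figure D3:**
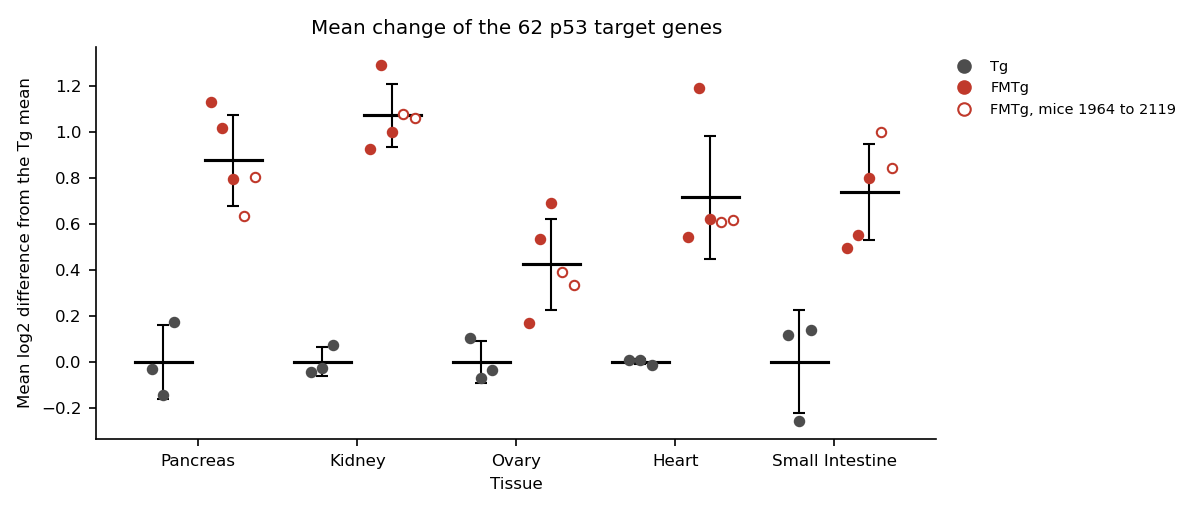
Mean log2 difference of the 62 p53 targets from the Tg mean of the tissue (y axis) by tissue (x axis). Points are libraries, bars are mean and SD, open points are low-numbered FMTg mice. Every FMTg library lies above every Tg library, with the smallest gap in the ovary (lowest FMTg 0.17, highest Tg 0.10).

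By function, the apoptosis list had 12, 13, 3, 6 and 11 of 15 members that rose in the pancreas, kidney, ovary, heart and small intestine, adjusted over the list alone. Among them were Eda2r, Phlda3, an inhibitor of Akt signalling, and Aen, a nuclease of apoptotic cells, in all 5 tissues, and Bax, the pore-forming effector of mitochondrial apoptosis, in 4. The cell cycle arrest list had 8, 8, 3, 4 and 7 of 12 members higher, with Gtse1, Psrc1 and Sesn2, a sestrin that restrains mTORC1, in all 5. Of 7 members of the negative feedback list, 4, 5, 3, 3 and 4 rose, with Mdm2, Trp53inp1 and Ccng1, the cyclin G1, in all 5 on the union of the lists. Members of a list need not all act as its name says, since Trp53inp1 promotes p53 activity. Repair and metabolism genes rose in 7, 8, 3, 2 and 6 of 16 cases; Polk, a translesion DNA polymerase, and Ercc5, an excision repair nuclease, were raised in all 5 tissues on the union. Secreted and membrane genes rose in 5, 5, 1, 5 and 2 of 12 cases. In the pancreas the mean of this list did not part the groups (difference 0.29, exact permutation p = 0.393). There 3 FMTg libraries lay above and 1 lay below all Tg libraries. Its camera call in the pancreas was lost with only mice with an ovary library (adjusted p = 0.0523). Gdf15, a circulating stress cytokine, rose adjusted over the list alone by 2.16 ± 0.44 in the pancreas, 2.48 ± 0.29 in the kidney, 2.05 ± 0.48 in the heart and 2.49 ± 0.54 in the small intestine. In the ovary it differed by 0.65 ± 0.34. Altogether 11 targets rose in all 5 tissues adjusted over the list alone, 9 of the 62 did so without the low-numbered mice, and 17 rose in none. Without those mice Phlda3, Aen and Ccng1 rose in 4 tissues, and Zfp365 was added to those in all 5. Within their own lists Mdm2, Trp53inp1, Ccng1, Aen, Phlda3, Polk and Ercc5 lost the ovary call when 1 or more of the single Tg replicates was left out. Mdm2, Trp53inp1 and Ccng1 also lost the heart call without each Tg replicate. The secreted and membrane list of the ovary lost its camera call without Tg replicate 3, FMTg replicate 2 or FMTg replicate 4 (adjusted p of 0.0761, 0.0510 and 0.0516), and without the low-numbered mice (0.194). The repair and metabolism list of the heart lost it without Tg replicate 1 (0.0687) and without the low-numbered mice (0.0682, median 0.09). With an estimated correlation none of the 5 functional lists passed in any tissue (adjusted p of 0.0635 to 0.379), with 0.246 for the secreted and membrane list of the ovary and 0.192 for the repair and metabolism list of the heart.

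**Figure D4:**
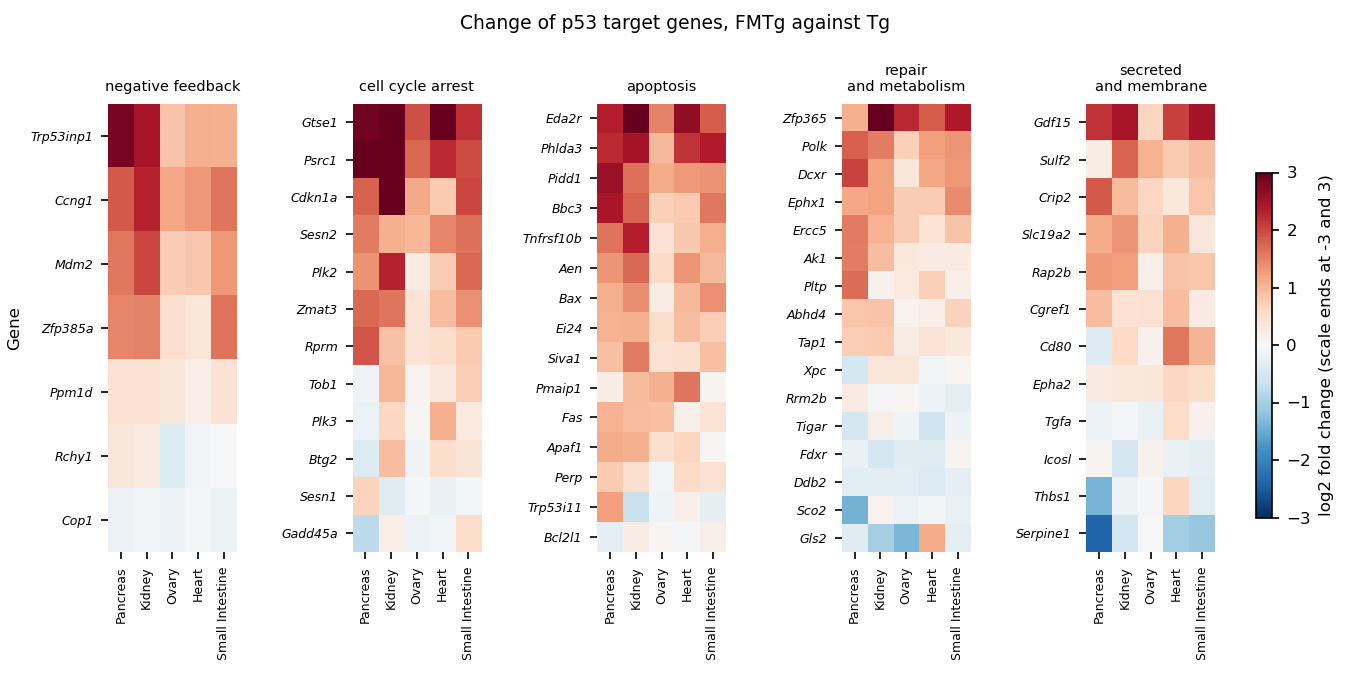
Log2 fold change, FMTg against Tg (colour), of each p53 target (y axis) in each tissue (x axis), 1 panel per list; the colour scale ends at -3 and 3. The list medians of all 62 genes run from 0.36 in the ovary to 1.06 in the pancreas.

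No single gene of the ovary passed the limma test over 16486 genes (smallest adjusted p = 0.183). At an unadjusted p below 0.05 there were 1049 genes, against 824 expected by chance, and voom on the recovered reads gave 0 genes past the threshold and 942 at the unadjusted level. Other settings did call genes: 17 with library weights, 51 with 1 model for all libraries, 3 without Tg replicate 2 and 1 without FMTg replicate 3. Among gene lists, steroidogenic genes of theca and luteal cells were lower in FMTg ovaries (median -0.84), and 4 of 10 fell adjusted over the list alone. Cyp11a1, which makes pregnenolone from cholesterol, fell by 1.63 ± 0.40, and Scarb1, the receptor that takes up high-density lipoprotein, fell by 0.78 ± 0.16. Akr1c18, which inactivates progesterone, fell by 4.25 ± 0.95, and Ptgfr, the receptor of prostaglandin F, fell by 3.07 ± 0.56. The list mean was lower in all 5 FMTg libraries than in any Tg library (exact permutation p = 0.0179), and camera gave an adjusted p of 1.43e-06, or 0.223 with an estimated correlation.

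Mitosis genes were higher in the ovary, with 23 of 23 FMTg means above the Tg means, a median of 0.84 and 7 members that rose adjusted over the list alone. Mki67, a marker of cycling cells, rose by 2.31 ± 0.49, the centromere genes Cenpe and Cenpf by 1.67 ± 0.47 and 1.88 ± 0.54, and Tpx2, a spindle assembly factor, by 1.70 ± 0.49. The adjusted p was 3.01e-14 at the preset correlation and 0.512 with an estimated correlation. Without Tg replicate 1 the median was 0.50, and without Tg replicate 2 it was 1.28. Mki67, Cenpe, Cenpf and Tpx2 lost their calls without Tg replicate 1, Tg replicate 3, FMTg replicate 1 or FMTg replicate 5, and no member passed without the low-numbered mice. That Tg replicate 1 drew 23.4% of its reads from acinar genes of the pancreas, against 0.0192% to 4.84% in the other ovary libraries. Of 8 adipocyte genes 6 rose (median 2.40): Cidec by 2.86 ± 0.74, Adipoq, the hormone adiponectin, by 2.72 ± 0.86, the lipid droplet protein Plin1 by 1.76 ± 0.59 and the protease Cfd by 2.67 ± 0.94. Their adjusted p was 1.47e-07, or 0.407 with an estimated correlation, and without the low-numbered mice the median was 1.28 with 1 member past the threshold. These 4 genes did not pass without Tg replicate 1, Tg replicate 2, FMTg replicate 4 or FMTg replicate 5. DNA replication genes (median 0.29, adjusted p = 1.76e-05), granulosa genes (0.51, 0.0145) and oocyte genes (0.73, 3.76e-04) had higher means and cytokine genes lower ones (-0.53, 9.29e-04), with no member past the threshold. With an estimated correlation the adjusted p values of these 4 lists were 0.761, 0.818, 0.781 and 0.492. The exact permutation p values of their list means were 0.214, 0.304, 0.196 and 0.107. For the means of the mitosis and adipocyte lists these were 0.0536 and 0.0714. Without Tg replicate 1 the granulosa median was -0.02 and the oocyte median 0.17, and neither list passed; the granulosa list also lost its call without FMTg replicate 1 (median 0.14) and without the low-numbered mice (adjusted p = 0.0894).

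In the heart 3 of 15769 genes changed, all higher and all p53 targets. Eda2r (chromosome X) rose 6.28-fold (log2 2.65 ± 0.13, adjusted p = 2.19e-04), Phlda3 (chromosome 1) 4.51-fold (2.17 ± 0.16, adjusted p = 0.00326) and Aen (chromosome 7) 2.51-fold (1.33 ± 0.13, adjusted p = 0.0163). At an unadjusted p below 0.05 there were 998 genes, against 788 expected by chance, and voom gave 2 and 934. Library weights gave 26 genes and 1 model for all libraries 22. Without the low-numbered mice the count was 1, and leaving out single libraries gave 1 to 4 genes, with 1 without Tg replicate 2. Eda2r kept its call in all 8 of these fits, Phlda3 in 7 and Aen in 2.

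Macrophage genes were higher in FMTg hearts, and 8 of 11 rose adjusted over the list alone (median 1.11). Adgre1, the antigen F4/80, rose by 1.15 ± 0.27, the receptor Csf1r by 1.07 ± 0.28, the protease Ctss by 1.39 ± 0.44 and the lysozyme Lyz2 by 1.11 ± 0.35. The adjusted p was 2.15e-10 at the preset correlation and 0.258 with an estimated correlation, and without the low-numbered mice no member passed. Adgre1, Csf1r, Ctss and Lyz2 also lost their calls without Tg replicate 1 or Tg replicate 2. Extracellular matrix genes had a median of 1.08 and fibroblast genes of 0.84, with no member past the threshold. Col3a1, a fibrillar collagen in both lists, differed by 1.88 ± 0.70. Their adjusted p values were 1.22e-07 and 9.24e-05, or 0.609 and 0.580 with an estimated correlation. Without FMTg replicate 2 the medians were 0.65 and 0.51. Of 13 genes of the unfolded protein response 6 rose (median 0.56), among them the chaperones Calr (1.13 ± 0.34) and Hsp90b1 (0.60 ± 0.18) and the secreted factors Creld2 (0.62 ± 0.14) and Manf (0.82 ± 0.26). Their list had an adjusted p of 4.56e-08, or 0.235 with an estimated correlation. Calr, Hsp90b1, Creld2 and Manf did not pass without any 1 of the Tg replicates. Oxidative phosphorylation genes had a median of -0.34 (adjusted p = 0.0124, 0.855 with an estimated correlation), and -0.12 without FMTg replicate 2 (adjusted p = 0.597). The exact permutation p of the list mean was 0.482 for oxidative phosphorylation genes and 0.0179 for genes of the unfolded protein response. Cardiomyocyte genes had a median of -0.19, with 0 of 12 past the threshold (adjusted p = 0.653).

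**Figure D5:**
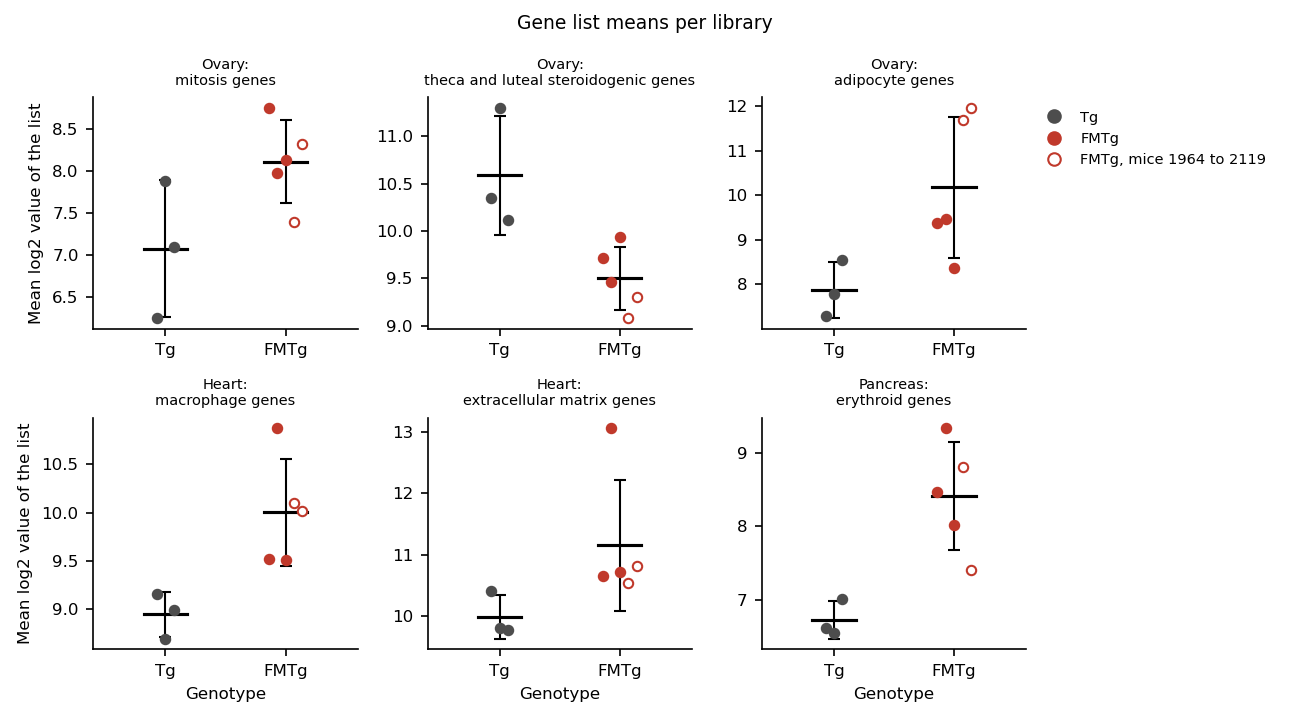
Mean log2 value of 6 gene lists per library (y axis) by genotype (x axis). Points are libraries, bars are mean and SD, open points are low-numbered FMTg mice. In the heart panels FMTg replicate 2 is the highest point (13.05 for extracellular matrix genes, where the next is 10.81).

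In the small intestine 0 of 16104 genes passed the limma test (smallest adjusted p = 0.558). At an unadjusted p below 0.05 there were 388 genes, against 805 expected by chance, and voom gave 0 and 385. Library weights gave 55 genes and 1 model for all libraries gave 29, and Mdm2 passed in both (adjusted p = 0.0465 and 0.00942). The 29 p53 targets that rose adjusted over the list alone included Phlda3 (2.38 ± 0.44), Gtse1 (2.19 ± 0.38), Psrc1 (1.95 ± 0.33), Plk2, a polo-like kinase (1.72 ± 0.29), and Bax (1.36 ± 0.24). B cell genes had lower means, 0 of 7 past the threshold, with a median of -1.18; Cd22 differed by -1.18 ± 0.44. This list had an adjusted p of 6.72e-05, or 0.313 with an estimated correlation. The median was -0.79 (2.54e-06) without the low-numbered mice, whose libraries had the lowest means of the list (4.63 and 5.41, against 6.04 to 6.58 in the other FMTg), and -0.73 (0.0264) without Tg replicate 2. Of 18 immediate early genes Egr1 alone rose adjusted over the list alone (1.03 ± 0.23), with a list median of 0.35 (adjusted p = 1.17e-04, 0.246 with an estimated correlation). Egr1 did not pass without the low-numbered mice, nor without Tg replicate 1, Tg replicate 2, Tg replicate 3, FMTg replicate 2, FMTg replicate 4 or FMTg replicate 5. DNA replication genes had a median of 0.18 (adjusted p = 1.36e-05, 0.717 with an estimated correlation) and no member past the threshold. Without Tg replicate 1 the median was 0.10 (adjusted p = 0.129), and without the low-numbered mice 0.05 (0.194). The exact permutation p of the list mean was 0.0714 each for B cell and immediate early genes and 0.268 for DNA replication genes. Intestinal stem cell genes (median -0.02, adjusted p = 0.288) and enterocyte genes (0.20, 0.298) had no member past the threshold.

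Across tissues, 0 of 14532 genes tested in all 5 were raised in all 5 by the limma test over all genes. In the pancreas and kidney, 63 and 92 of 14721 genes rose and 35 rose in both, against 0.394 if the lists were independent. The same 3 Tg mice and the same mice of FMTg replicate 2 and FMTg replicate 3 gave both tissues, from separate libraries, so independence is not given. In the other 55 splits of the libraries, made the same way in both tissues, 0 genes rose in both. Those splits called at most 2 genes in the pancreas and 7 in the kidney, so this does not test the sharing. In the model of all 40 libraries 122 of 17284 genes had a mean change over the 5 tissues, 114 higher and 8 lower. Of the 114, 110 had the same sign in every tissue, and 110 were also higher without the low-numbered mice. The largest mean rises were those of Gtse1 (3.06 ± 0.22), Psrc1 (2.54 ± 0.21), Ano3 (2.45 ± 0.49), Eda2r (2.30 ± 0.12), Plcd4, a phospholipase C (2.16 ± 0.44), and Zfp365 (2.14 ± 0.46). Fam196a, Phlda3, Ddias, Gdf15, Svop, Inka2, Cdkn1a, Sncg, Ccng1, Celf5, Trp53inp1, Pidd1, Bbc3 and Scn3b followed, with means from 2.11 to 1.48. The place of Sncg among them rests on the low-numbered mice, since its mean of 1.81 was 0.92 without them. Plcd4, Zfp365, Sncg and Celf5 did not pass when any single Tg replicate was left out. Ano3 did not without Tg replicate 1 or Tg replicate 2, nor Fam196a and Scn3b without Tg replicate 2. The same held for Zfp365, Sncg and Celf5 without FMTg replicate 5, Sncg without FMTg replicate 4 and Celf5 without FMTg replicate 2. Lower means were found for Bmf, a BH3-only protein (-0.71 ± 0.13), Grk3, a receptor kinase (-0.69 ± 0.15), Insr, the insulin receptor (-0.46 ± 0.10), Naa25, Ranbp9, Sgms1 and Acp1 (-0.38 ± 0.09). Without the low-numbered mice Grk3 fell to -0.40, Naa25 to -0.28 and Ranbp9 to -0.19, and Acp1 did not pass (adjusted p = 0.0687). Of these 7 genes Bmf alone passed without each Tg replicate. The number of genes with a mean change was 63, 55 and 66 without Tg replicate 1, Tg replicate 2 and Tg replicate 3 of every tissue, and 191 without FMTg replicate 2. The falls varied more than the rises. There were 1, 1 and 3 falls without Tg replicate 1 to Tg replicate 3, and 33, 50, 19, 5 and 4 without FMTg replicate 1 to FMTg replicate 5. Rises numbered 54 to 141 over these fits. With the low-numbered mice left out there were 273 rises and 33 falls.

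The F test of differences between tissues (limma) passed for 23 genes, and for 12 without the mouse block. It passed for 22 in simulated reads with no gene changed. Those were fitted without mouse correlation, so 23 and 22 come from unlike fits. Single genes below need other evidence. Trp53inp1 had log2 changes of 2.79 in the pancreas and 2.46 in the kidney against 0.86 to 1.10 elsewhere (adjusted p = 1.54e-04). Inka2 changed by 2.89 and 3.42 there and by 0.48 in the heart (2.63e-04). Eda2r changed most in the kidney (3.19) and least in the ovary (1.51; 0.00419), and Gtse1 ranged between 4.92 in the kidney and 1.99 in the ovary (0.00549). Obp2b changed by 4.73 in the pancreas and by -0.13 to 0.44 elsewhere (5.21e-04), and Susd6 by 0.95 and 0.75 in the pancreas and kidney against 0.11 to 0.38 (0.00370). Trim7, a ubiquitin ligase, ran from -0.46 in the heart to 2.10 in the pancreas (0.00539), Map3k20 from -0.25 in the heart to 1.03 in the pancreas (0.00549) and Fgfr3 from -0.57 in the small intestine to 1.48 in the pancreas (0.00549). Leaving out the low-numbered mice gave 8 differing genes, 4 of them among the 23, and among the 9 named here Obp2b and Susd6 still passed. Leaving out 1 replicate of every tissue gave 9, 5 and 7 genes for Tg replicate 1, Tg replicate 2 and Tg replicate 3. It gave 11, 47, 46, 12 and 12 genes for FMTg replicate 1 to FMTg replicate 5.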

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

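Of the tests in this part, the splits of the pancreas, kidney and heart counts, of the mean change, of the differing genes and of the other lists, and the tests of GC content and transcript length were set before their results were seen. The tests of sex, of library complexity, of the ovary and heart lists, and the splits behind the counts of 0 and behind the genes shared by pancreas and kidney were chosen after.

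In 14 of 126 groups of 5 FMTg libraries, 1 library lay far from the others, where chance gives about 1 in 20 groups, or 6.3 here. The groups share libraries and genes, so 14 against 6.3 does not measure an excess. The values below are the gap to the nearest library divided by the range of the group. FMTg Heart replicate 2 was highest for the p53 score (0.880; 1.19 against 0.62 in the next), the p53 targets of cell cycle arrest (0.804), apoptosis (0.740) and the secreted and membrane list (0.893), and for extracellular matrix genes (0.890), and lowest for cardiomyocyte genes (0.733). FMTg Heart replicate 4 was highest for the unfolded protein response (0.779). FMTg Kidney replicate 2 was highest for Mdm2 (0.722) and for the p53 targets of apoptosis (0.732) and of repair and metabolism (0.740), and FMTg Kidney replicate 1 was lowest for Serpina3m (0.716). FMTg Kidney replicate 3 had the highest share of acinar reads (0.883; 1.79% against 0.212%). FMTg Pancreas replicate 4 had the fewest reads (0.737; 7.16 M against 12.1 M), and FMTg Small Intestine replicate 2 was lowest for enterocyte genes (0.864).

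The F test of differences between tissues passed for Trp53inp1 (limma, adjusted p = 1.54e-04), Inka2 (2.63e-04), Obp2b (5.21e-04), Susd6 (0.00370), Eda2r (0.00419), Trim7 (0.00539), and Gtse1, Map3k20 and Fgfr3 (0.00549 each). In simulated reads with no gene changed, fitted without mouse correlation, this test called 22 genes. Reads outside the comparisons also carried signal. Y-linked genes reached 247 reads per 1e+06 in an FMTg library and at least 45.1 in the 9 libraries of 5 male mice, against at most 3.10 in the other FMTg and 2.33 in Tg libraries. Acinar genes of the pancreas took 23.35% of the reads of Tg Ovary replicate 1, against at most 4.84% in the other ovary libraries and 3.75% in kidney, heart and intestine.

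Other ways to divide the 8 libraries of a tissue into 3 and 5 tested whether chance can give such counts. A chance division is argued against for the pancreas, where only the real split, 1 of 56, gave as many genes (68, highest other 2), and for the kidney (1 of 56, with 95, highest other 7). That is the smallest possible share. All low-numbered and all male mice are FMTg, so the splits do not tell genotype from mouse number or sex. The genes raised in both (1 of 56, with 35, highest other 0) add no test, because the other splits called at most 2 genes in the pancreas. Chance cannot be excluded for the heart, where 4 of the 56 splits gave at least the real 3 genes (highest other 547). For the counts of 0 in the ovary (56 of 56 splits, highest other 6), in the small intestine (56 of 56, highest other 2029) and of genes raised in all 5 tissues (56 of 56, highest other 0), every split gives at least 0 genes, so these comparisons say nothing about chance. Chance cannot be excluded for the 122 genes with a mean change (7 splits, highest other 3453) or the 23 differing genes (10 splits, highest other 1685). Nor can it for the 75 pairs of tissues and lists other than the union of p53 targets (18 splits, highest other 107). The functional p53 lists are counted among these pairs. The 6 other splits as large for the mean change all put both library positions of low-numbered mice (FMTg replicate 4 and FMTg replicate 5) into the group of 3, which points to a structure of the samples; with 0 or 1 of these positions in that group the highest other was 1. Among the 3 other FMTg and the 3 Tg libraries there are 10 splits, too few for a share under 0.05 (pancreas 109, highest other 0; kidney 123, highest other 2; ovary 0 and 0; heart 1, highest other 112; small intestine 0 and 0).

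The FMTg libraries of low-numbered mice stand apart from the other FMTg libraries, with 5, 4422, 648, 133 and 2144 genes differing in the pancreas, kidney, ovary, heart and small intestine. Sex is argued against as the whole cause in the ovary, where 648 genes differed and all mice are female. No other of the 10 splits of those 5 FMTg ovary libraries gave any (highest other 0). The group was set apart from these same data, so that comparison of splits is no independent test. In the kidney, heart and small intestine the 2 low-numbered libraries are the 2 male ones, and in the pancreas both are male. Sex and mouse number therefore cannot be told apart in the kidney, heart and small intestine. GC content is argued against as the whole cause by a Spearman rho across genes of 0.00147 in the ovary, with 0.172, 0.0446, 0.0122 and 0.313 in the pancreas, kidney, heart and small intestine; genes are not independent replicates. A library batch of lower complexity stays open. All 10 of the 10 low-numbered libraries showed fewer genes at equal depth than every other library of their tissue, but they were set apart because of their many genes without reads, so this count is no test of a batch. Transcript length stays open too (rho of 0.070 in the pancreas and -0.0945 to -0.169 in the others), as do age of the samples and litter, which were not tested.

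Mitosis genes were higher in the FMTg ovary. Pancreatic RNA in Tg Ovary replicate 1 stays open as a cause. Without that library 58.7% of the median remained (0.50 of 0.84) and the list passed at the preset correlation, but the list means did not part (0.63, exact permutation p = 0.190, 21 splits). With all libraries and an estimated correlation the list did not pass (adjusted p = 0.512). More granulosa cells in some ovaries may contribute: over the 8 libraries the granulosa and mitosis means were correlated within groups (Pearson r 0.777, exact permutation p = 0.0444; Spearman rho 0.714, exact permutation p = 0.0736; 720 permutations), but r was 0.414 without the 2 farthest libraries, on which the relation rests. Chance cannot be excluded, since 3 of the 56 splits gave as large a difference (1.04, highest other 1.30). An effect of genotype stays open.

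Macrophage and matrix genes were higher in the FMTg heart. A single library, FMTg Heart replicate 2, is argued against as the whole cause for these 2 lists. Without it the lower of the 2 medians kept 60.0% of its value and both lists passed at the preset correlation. The list means still differed (0.84 and 0.69, exact permutation p = 0.0286 each, the smallest possible over 35 splits). With all 8 libraries the exact permutation p was 0.0357 for macrophage genes and 0.0893 for matrix genes. The matrix mean therefore did not pass this test with FMTg Heart replicate 2 included. For fibroblast genes it stays open (61.1% of the median kept; 0.57, exact permutation p = 0.0571). With all libraries and an estimated correlation none of the macrophage, matrix and fibroblast lists passed (adjusted p of 0.258, 0.609 and 0.580). A lower share of cardiomyocyte RNA stays open: the macrophage list rose by 0.72 more than the endothelial list (exact permutation p = 0.0536, highest other 0.762), and of a set of 8 such comparisons with other cell types, the rest of them run after this one, none passed (adjusted p of 0.179 to 0.714). A lower share would raise all other cell types alike, and their list means moved apart: macrophage 1.06, fibroblast 0.91, B cell 0.36, endothelial 0.35, T cell and NK cell 0.11, smooth muscle 0.07, adipocyte 0.07, erythroid -0.25 and neutrophil -1.13. Cardiomyocyte means lay within or above the Tg range in 4 of the 5 FMTg hearts (15.31 to 15.78, against 15.09 to 15.62 in Tg), and the mean was 14.05 in FMTg replicate 2. That library also had the highest matrix mean (13.05), which a lower cardiomyocyte share would give. These values do not decide on that explanation. None of the 8 comparisons passed, the spread between libraries is wide and a small loss would not show at so high a level. A chance division is argued against for the macrophage list taken alone, with 2 of the 56 splits as large (1.06, highest other 1.16). That list was picked among 222 pairs of list and tissue. An effect of genotype on resident or infiltrating macrophages may be involved and was not tested apart from cell shares.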

How the results depend on the processing

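Leaving out the low-numbered mice, the term for them, voom and the mean change over tissues were chosen after seeing the data; the other alternatives were fixed beforehand. The cause of the changes below was not tested, except that fewer samples enter when mice are left out. Mdm2 in the kidney passed and every p53 list median was positive under all alternatives run, but their sizes moved. The p53 median of the small intestine was 0.41 with library weights, against 0.71. Mdm2 was 1.22 in the ovary and 1.24 in the heart with only FMTg mice numbered no lower than the Tg mice, against 0.77 and 0.80, and passed in neither (adjusted p = 0.594 and 0.573). Without the variance trend the pancreas had 10 genes, Mdm2 there missed the threshold (1.59, adjusted p = 0.165) and 14 genes differed between tissues. With library weights the counts were 568, 211, 17, 26 and 55 in the pancreas, kidney, ovary, heart and small intestine, 3 genes were raised in all 5, 1331 differed, 350 had a mean change, and Mdm2 passed in the small intestine (0.96, 0.0465). With 1 model for all libraries the counts were 390, 59, 51, 22 and 29, and Mdm2 passed in the small intestine (1.30, 0.00942). Only mice with an ovary library, all of them female, gave 2 genes in the pancreas, 1 in the heart and 204 with a mean change. Mdm2 in the pancreas was 1.83 in that subset (adjusted p = 0.0670). Only FMTg mice numbered no lower than the Tg mice gave 109 in the pancreas, 0 in the heart, 0 differing and 250 with a mean change. Without the low-numbered mice these were 109, 1, 8 and 306, and voom without them gave 1 in the heart. Without the mouse block 12 genes differed and 343 had a mean change. With an estimated correlation the union of p53 targets, with medians of 1.06, 0.95, 0.36, 0.68 and 0.71, no longer passed (0.0635, 0.0635, 0.143, 0.108, 0.0665). The 75 pairs of all other lists (17, 11, 14, 20 and 13 by tissue), the functional p53 lists among them, became 0, with 0 in each tissue.

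Replicate numbers do not pair the libraries: of 15 same-numbered pairs 6 correlated above 0.1 (range -0.587 to 0.592), and 3 of the Tg libraries matched their own number best. With the number as a block the pancreas and heart had 0 genes each, and Mdm2 in the pancreas was 1.87 (adjusted p = 0.0987).

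Leaving out 1 library at a time gave 9 to 93 genes in the pancreas, 46 to 94 in the kidney, 0 to 3 in the ovary (3 without Tg replicate 2, 1 without FMTg replicate 3), 1 to 4 in the heart and 0 to 0 in the small intestine. Mdm2 ran from 1.45 to 1.78, 1.86 to 2.06, 0.64 to 0.85, 0.62 to 0.93 and 1.17 to 1.41 in the same order of tissues, and the p53 medians from 0.95 to 1.11, 0.91 to 1.05, 0.33 to 0.43, 0.54 to 0.78 and 0.55 to 0.78. Leaving 1 replicate number of 1 genotype out of every tissue together gave 0 to 0 genes raised in all 5, 5 to 47 differing and 55 to 191 with a mean change.

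Reversals concern values without a call, apart from 2 lists that lost theirs. Trp53 changed sign in the pancreas with median centring (0.0029), library weights (0.088), only mice with an ovary library (0.083) and without FMTg replicate 3 (-0.17 to 0.038 over the fits that left out a library). In the ovary it did so with median centring (0.0016) and without Tg replicate 2 (0.0060), FMTg replicate 1 (0.019) or FMTg replicate 3 (range -0.086 to 0.072). In the heart it did so with library weights (-0.0060) and without Tg replicate 3 (-0.0099 to 0.26). In the small intestine it did so with library weights (-0.075), a replicate block, only mice with an ovary library, without low-numbered mice and with a term for them (-0.0136 each), and voom without them (-0.0138). Inha in the ovary was -0.037 with only FMTg mice numbered no lower than the Tg mice, and Rrm2 in the small intestine -0.038 with library weights. The granulosa list of the ovary was -0.017 without Tg replicate 1 (range -0.017 to 1.00), and the DNA replication list of the small intestine -0.018 with library weights. Among list members named in the text, 147 comparisons that left out a library lost a call and 24 gained one.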

Other observations

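Digestive enzyme genes of the pancreas were also read outside it. The median log2 difference of the acinar list was -2.91 in the kidney, -3.37 in the ovary, -3.07 in the heart and -0.84 in the small intestine, with no member past the threshold. Camera gave adjusted p values of 0.0260, 0.00181, 4.55e-06 and 0.00181, or 0.877, 0.818, 0.744 and 0.818 with an estimated correlation. Without the low-numbered mice it was -0.08, -0.31, -1.11 and -0.19. In the ovary, Tg replicate 1 alone held 23.35% acinar reads, against 0.0192% to 4.84% in the other libraries. The mean of the list was 15.43, 9.83 and 8.18 in the Tg ovaries and 7.69, 11.81, 13.07, 5.19 and 3.65 in the FMTg ovaries, so the groups overlap. Acinar reads made up 0.00221% to 3.75% of the libraries of kidney, heart and intestine.

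The share of mitochondrial reads was higher in the low-numbered libraries of the kidney (mean 6.04% against 2.76% in the other libraries), ovary (1.83% against 0.788%), heart (13.3% against 6.30%) and small intestine (2.63% against 1.69%). In the pancreas it was 0.402% against 0.327%.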
